A study of Arabidopsis thaliana with 12 samples.

How the data were processed

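The 12 libraries are described in the series record as 3 biological replicates of each of 4 groups, each replicate a pool of about 20 organs. Plants were grown on rockwool with a nutrient solution at 21 °C in 16 h light and 8 h dark, and RNA was extracted with CTAB and lithium chloride. Libraries were made with a stranded TruSeq kit after enrichment of mRNA and sequenced as pairs of 150 bases on a NovaSeq. Per the submitters' processing notes, reads were mapped to TAIR10 with STAR 2.7.0b and assigned to genes with featureCounts 1.6.0. The deposited table holds counts of read pairs or reads per gene, and the authors give the unit as counts; its values are whole numbers, and no processed fold changes were used. Trimming, the handling of reads with several positions and the strand setting of the counting step are not given in the sources used here.

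A pipeline of spliced alignment and gene-level counting fits poly(A)-enriched RNA, and the kit keeps the strand of the transcript. Of 38 pairs of genes on opposite strands that overlap by at least 90% of the exonic length of both, 37 had counts within 10% of each other, with a median ratio of 1.00. Counts in the table therefore did not separate the strands, and a gene that overlaps another on the opposite strand shares its reads. Exonic overlap was found for 37 of the 140 named genes and a near-identical stretch in another gene (at least 100 bases at 95% identity, blastn 2.17.0) for 5. Gene symbols, biotypes and exonic lengths came from the TAIR10.1 annotation, which matched 36632 of the 36917 gene identifiers in the table. It may differ in detail from the build used for counting, so no coordinates are given. Genes were ordered by locus code, and neighbours are neighbours in that order. Some codes do not follow position: AT1G07887 overlaps AT1G53480 (MRD1).

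Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. For each comparison of mutant and wild type within a tissue, genes were kept by filterByExpr, libraries scaled by TMM, and group means compared with edgeR's quasi-likelihood F test with robust estimation off and the Benjamini-Hochberg (BH) adjustment at 0.05. The difference of the effect between tissues was the contrast of both effects in a fit of all 12 libraries, and the wild types were compared in a fit of their 6. SE is the fitted log2 fold change divided by the square root of F. CPM values (counts divided by the scaled library size, as cpm in edgeR gives them) are TMM-scaled with the factors of the fit they are printed beside, so a gene's CPM differs slightly between fits; CPM of the run of 7 neighbouring genes in the figure, and where stated, are unscaled. P-values measure the spread between these samples only, and exact counting intervals and floors cover counting error only. Where a group had 0 counts, a ratio is given as a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio of counts per total count is given with its exact 95% interval. The fitted fold change of such genes depends on the small default prior count of edgeR's fit and is no bound.

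A set of 23 gene lists was fixed before the count table was seen, from general knowledge of flower, fruit and meristem biology, and includes markers of other cell types the dissections could hold. Lists with at least 5 tested members were tested with camera on log2 CPM at a preset inter-gene correlation of 0.01, with BH adjustment over lists. Camera with an estimated correlation and fry were run as alternatives. For each list the members past edgeR's threshold are counted, and those past it when p-values are adjusted over the list alone. Overlap of calls between tissues was tested with Fisher's exact test in each pair of directions, adjusted over the 4 pairs.

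Named genes follow a rule fixed in advance: FUL first, then the 10 largest changes in each direction among called genes with a mean of at least 2 CPM in the higher group and no overlap between replicates, up to 4 called members per list by lowest p or the 1 with the lowest p where none was called, the 5 largest in each direction for the difference, up to 10 called in both tissues, and IND, SHP1, SHP2, ALC, SVP, SOC1, AGL24, AP2 and SAUR10. Of these, 128 were tested in pistils, 126 in meristems and 138 in the difference, where 37 passed, 14 higher and 23 lower in pistils. Genes outside the rule were chosen after their values had been seen, among them ERL1, OST1, MYB60 and KAT1.

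Alternatives fixed in advance were size factors of DESeq2 in edgeR, DESeq2 itself, no filter, a stricter filter (1 CPM in 3 libraries), a fit of all 12 libraries, a threshold of 1 on the absolute log2 fold change, omission of organelle genes, and omission of each library in turn. After the data were seen, 3 additions were made: the overlap of calls without ful-1 pistil library 3, genes named by the same rule from the pistil and difference fits without it, and lists of iron genes. Blocks by replicate could not be fitted because the columns carry no replicate numbers. As a check of groupings, tests were repeated on other splits of the same libraries: all 10 splits of 6 libraries into 3 and 3, and 100 of the 200 possible for the difference.

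The code was tested on simulated data with 100 genes set to change 2-fold and 100 genes set to change 4-fold. Counts were drawn at the trended dispersion of each fit, without the spread of single genes around it. EdgeR recovered 5% of the 2-fold and 38% of the 4-fold changes in pistils with 6 libraries, 87% and 100% with 5, and 87% and 100% in meristems. For the difference it recovered 2% and 55%, and for the wild types 91% and 99%, with 1 to 11 false calls in each of these 5 runs. A gene that does not pass in pistils with 6 libraries is thus poorly tested. Real genes also vary around the trend, so the shares recovered can be too high. In meristems the ferritin gene FER1, at -2.14 ± 0.39 (log2, SE), did not pass (edgeR adjusted p of 0.102). A gene that does not pass in the other fits is therefore not shown to be unchanged.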

Results

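Expression in Arabidopsis thaliana was profiled by RNA sequencing in 12 libraries, 3 biological replicates in each of 4 groups. The mutants lack function of FRUITFULL (FUL), a MADS-domain transcription factor with known roles in fruit valve growth and in the inflorescence meristem. Pistils and young siliques of floral stages 12 to 16 came from wild-type Landsberg erecta (Ler) and from ful-1, listed with the same ecotype. Dissected inflorescence meristems, with buds up to stages 3 to 4, came from wild-type Columbia (Col-0) and from the T-DNA line ful-7. Each sample pooled about 20 organs. Total counts were 58594593, 38340498 and 59830057 in Col-0 libraries 1 to 3, and 83606724, 47262598 and 72506262 in ful-7. They were 30528403, 31977805 and 34276079 in the Ler pistils, and 38215149, 27545430 and 13191949 in the ful-1 pistils. The deposited columns carry no replicate numbers, so libraries are numbered within a group by their order in the table.

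The ful-1 pistil library with the lowest total, library 3 with 13191949 counts, stood apart from the other pistil libraries. Its counts correlated with those of the other 5 pistil libraries at Spearman's rho of 0.910 to 0.916 across genes, against 0.977 to 0.986 among those 5. Genes are not independent replicates, so these values carry no test. Plastid genes took 2.04% of its counts, against 0.118% to 0.394% in the other 5, and its 50 most abundant genes took 26.8%, against 8.33% to 10.6%. The biological coefficient of variation of the pistil fit was 0.413 with this library and 0.157 without it, so counts and list results for pistils are given both ways, and values of single genes from the fit named beside them.

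The FUL transcript was lower in both mutants than in their wild types. It stood at 101.2 ± 5.11 CPM (library-scaled counts) in Ler pistils and at 6.95 ± 3.56 CPM in ful-1 pistils (SD, n = 3 each), 6.87% of the wild-type level. In meristems it stood at 118 ± 30.6 CPM in Col-0 and at 2.47 ± 0.789 CPM in ful-7 (SD, n = 3 each), 2.09% of wild type. Each mutant library lay below each wild-type library of its tissue, and the lowest count in a mutant library was 25. The log2 fold change was -5.56 ± 0.29 (SE) in meristems, with an adjusted p of 0.00036 in edgeR's quasi-likelihood test. In pistils it was -3.84 ± 0.47 (SE) over 6 libraries, where the edgeR adjusted p of 0.063 missed the threshold, and -3.50 ± 0.11 (SE) without ful-1 library 3, where it was 0.00015.

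**Figure D1:**
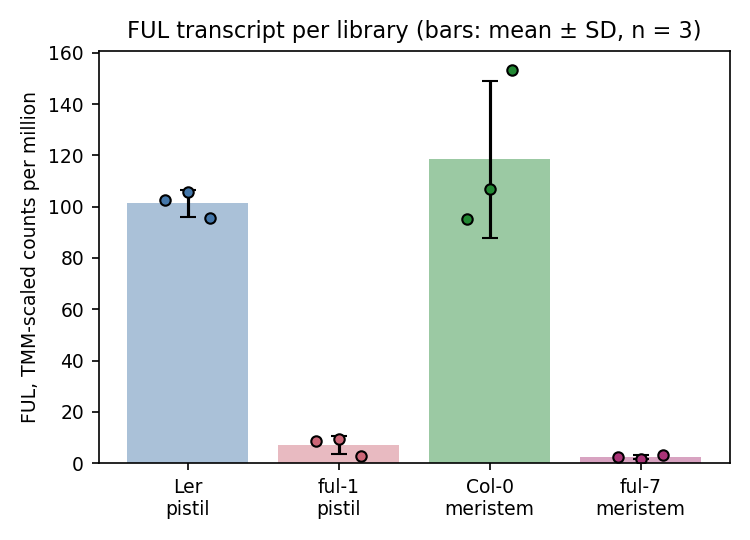
FUL transcript level in TMM-scaled CPM (y axis, from 0) in the 4 groups (x axis); points are libraries, bars are means and error bars SD of 3 libraries. The ful-1 libraries lie at 2.89 to 9.49 CPM and the ful-7 libraries at 1.71 to 3.28 CPM, below all wild-type libraries of the same tissue.

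The pistil comparison asks which transcripts depend on FUL in the developing fruit. INDEHISCENT (IND, AT4G00120), a bHLH gene that specifies the valve margin where the fruit opens, rose from 5.55 ± 0.487 CPM in Ler to 64.2 ± 10.1 CPM in ful-1 (SD, n = 3 each). Its log2 fold change was 3.53 ± 0.23 (SE), with an edgeR adjusted p of 0.010. Of the stomatal lineage, FAMA, a bHLH regulator of guard cell fate, fell from 9.37 ± 1.13 to 1.51 ± 0.193 CPM, and POLAR, a polarity protein of dividing stomatal precursors, fell from 2.71 ± 0.430 to 0.216 ± 0.0211 CPM (SD, n = 3 each). Among 23674 genes tested, 44 passed, 20 higher and 24 lower in ful-1; 36 were annotated as protein coding, 4 as pseudogenes or transposable elements and 0 as organelle genes. By edgeR, 2429 genes had an unadjusted p under 0.05, and DESeq2 called 872 genes.

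The 10 genes with the largest increases in ful-1 pistils each lay under 1 CPM in Ler. The ubiquitin-conjugating enzyme gene UBC9 rose from 0.188 ± 0.0184 to 50.8 ± 12.7 CPM (SD, n = 3), and AT4G27940 by 5.47 ± 0.37 (log2, SE). YLMG1-2 had 0 counts in the 3 Ler libraries and 1295 in the 3 ful-1 libraries, at least 529-fold higher against a floor of 3 counts over the group. AT4G27980 had 3 counts in Ler and 3066 in ful-1, a ratio of 1253 (95% exact counting interval 428 to 6078). SLAH2, of the SLAC1 family of anion channels, had 1 count and 199 counts, a ratio of 244 (43.3 to 9683). These 5 genes lie within a run of 7 neighbouring genes, from AT4G27940 to AT4G28000, that were all near 0 in Ler. UBC9 lay at 75.2 CPM (without TMM scaling) in Col-0 meristems, where FUL is wild type. Tissue and ecotype differ there, so these increases cannot be assigned to FUL rather than to the Ler strain. In meristems the 6 tested genes of the run had log2 fold changes of 0.03 ± 0.10 (YLMG1-2) to 1.03 ± 0.28 (SLAH2; SE) and did not pass edgeR's test (adjusted p of 0.912 and 0.215 for these). AT3G27473 had 3 counts in Ler and 1470 in ful-1, a ratio of 601 (205 to 2916), and AT2G06002, a non-coding RNA, rose by a log2 fold change of 8.04 ± 0.84 (SE). The remaining increases among the 10 largest were AT4G14548, another non-coding RNA, at 4.83 ± 0.48, and the pair AT3G22125 and AT3G22142, at 4.17 ± 0.28 and 4.17 ± 0.28 (log2, SE). This pair overlaps over 96.5% of the exonic length of AT3G22125 and thus shares counts. EdgeR adjusted p values of these 10 genes ran from 0.0053 to 0.036, and their libraries did not overlap between genotypes, as the rule that named them required.

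**Figure D2:**
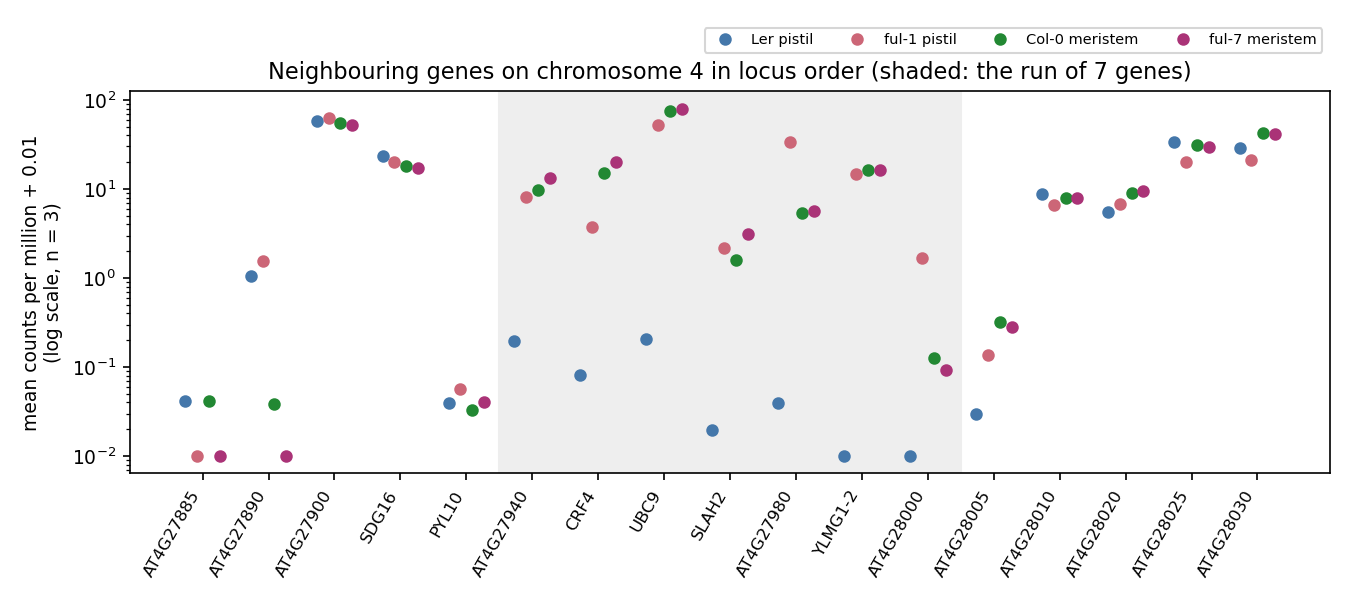
Mean CPM without TMM scaling, plus 0.01 (y axis, log scale) of 17 genes in order of locus code (x axis) in the 4 groups (colours, mean of 3 libraries each), with the run of 7 genes shaded. AT4G07925, which overlaps CRF4, is not shown because its code lies elsewhere in that order. Within the run UBC9 lay at 0.197 CPM in Ler pistils and at 52.4, 75.2 and 80.0 CPM in ful-1 pistils, Col-0 meristems and ful-7 meristems.

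The strongest decreases in ful-1 pistils were of other kinds of genes. AT2G00560, annotated as a miscellaneous RNA, had 2887 counts in Ler and 2 in ful-1, a ratio of 1178 (95% exact counting interval 326 to 9728). AT1G04660 fell from 29.6 ± 13.8 to 0.0918 ± 0.0898 CPM (SD, n = 3). MRD1, its overlapping antisense RNA AT1G07887 and HEI10, a meiotic crossover factor, had log2 fold changes of -6.56 ± 0.41, -6.62 ± 0.44 and -4.12 ± 0.42 (SE). MRD1 shares 83.1% of its exonic length with AT1G07887 and 73.8% with HEI10, and overlapping genes shared counts here. CORI3, a cystine lyase induced by jasmonate, changed by -5.11 ± 0.56, PKS2, a phytochrome kinase substrate, by -4.77 ± 0.38, and CGA1, a GATA factor of chloroplast development, by -4.17 ± 0.30 (log2, SE). The serine carboxypeptidase-like gene SCPL9 changed by -3.97 ± 0.38 and POLAR by -3.64 ± 0.33 (log2, SE). The edgeR adjusted p values of these 10 genes ran from 0.010 to 0.045, and the same rule named them. AT1G04660 stood at 5.78 ± 1.29 CPM in Col-0 and 9.46 ± 0.794 CPM in ful-7 meristems (SD, n = 3), so its fall was not seen there. Only ful-1 was profiled among mutants in pistils. For pistil calls outside the run too, a difference between the strains thus cannot be told apart from loss of FUL.

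Omission of each library in turn was planned, but giving values without ful-1 library 3 throughout was decided after seeing the data. Leaving it out raised the pistil count to 3221 of 24068 genes, 1233 higher and 1988 lower, and the 44 genes above were all called again in the same direction. Leaving out any other pistil library left 0 calls (Ler 1, 2 or 3, or ful-1 library 1) or 1 call (ful-1 library 2), while by the same edgeR test 1093 to 2968 genes had an unadjusted p under 0.05.

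Of 34 tested genes of fruit patterning and the dehiscence zone, 1 rose in ful-1 pistils, 0 fell and 33 did not pass over 6 libraries, and 1 rose when adjusted over the list alone. Camera gave the list an adjusted p of 0.016 upwards, and adjusted p = 0.828 with an estimated correlation. Without ful-1 library 3, 11 rose, 0 fell and 23 did not pass, and adjusted over the list alone 13 rose and 1 fell. Camera then gave 0.00017 upwards, with adjusted p = 0.450 with an estimated correlation. In that fit the valve margin MADS-box genes SHP1 and SHP2 rose from 88.4 ± 8.14 to 243 ± 2.66 CPM and from 72.3 ± 9.08 to 141 ± 5.02 CPM (SD, n = 3 and 2). Their log2 fold changes were 1.46 ± 0.10 and 0.96 ± 0.12 (SE). The bHLH genes SPT and ALC, which act in carpel margin tissues and the separation layer, rose by 1.26 ± 0.09 and 0.90 ± 0.14, and the AP2 gene by 1.15 ± 0.15 (log2, SE). The edgeR adjusted p of these 5 genes ran from 0.0022 to 0.013 in the 5 libraries, and from 0.241 to 0.632 in all 6. ALC shares 84.5% of its exonic length with AT5G67100 and SHP2 56.7% with AT2G42835, and the counts of such pairs are not separated here. The meristem regulators SOC1, SVP and AGL24, with log2 fold changes of -0.70 ± 0.30, 0.74 ± 0.30 and 0.53 ± 0.38 (SE) in the 5 libraries, did not pass in pistils in either fit. SAUR10 had too few counts to be tested in either tissue.

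Stomatal lineage and guard cell genes formed the list with the lowest camera p in pistils over 6 libraries. Of 22 tested members, 0 rose, 2 fell and 20 did not pass over 6 libraries, and adjusted over the list alone 2 rose and 10 fell. Camera gave an adjusted p of 0.00035 downwards, with adjusted p = 0.197 with an estimated correlation. By edgeR 13 of the 22 had an unadjusted p under 0.05. Without ful-1 library 3, 12 fell, 4 rose and 6 did not pass (12 and 4 also when adjusted over the list alone), at a camera adjusted p of 0.00042 and adjusted p = 0.450 with an estimated correlation. The genes that fell included MUTE, which ends the divisions of stomatal precursors, at -5.49 ± 0.29, and the receptor-like gene TMM at -2.73 ± 0.20 (log2, SE). The myrosinase gene TGG1, abundant in guard cells and myrosin cells, also fell, at -3.04 ± 0.18 (log2, SE). The 4 that rose were the potassium channel gene KAT1 at 2.31 ± 0.32, MYB60 at 0.74 ± 0.18, the receptor kinase gene ERL1 at 0.65 ± 0.14 (log2, SE) and the kinase gene OST1. KAT1, MYB60 and OST1 are known from mature guard cells, and these 4 were named after their values had been seen.

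**Figure D3:**
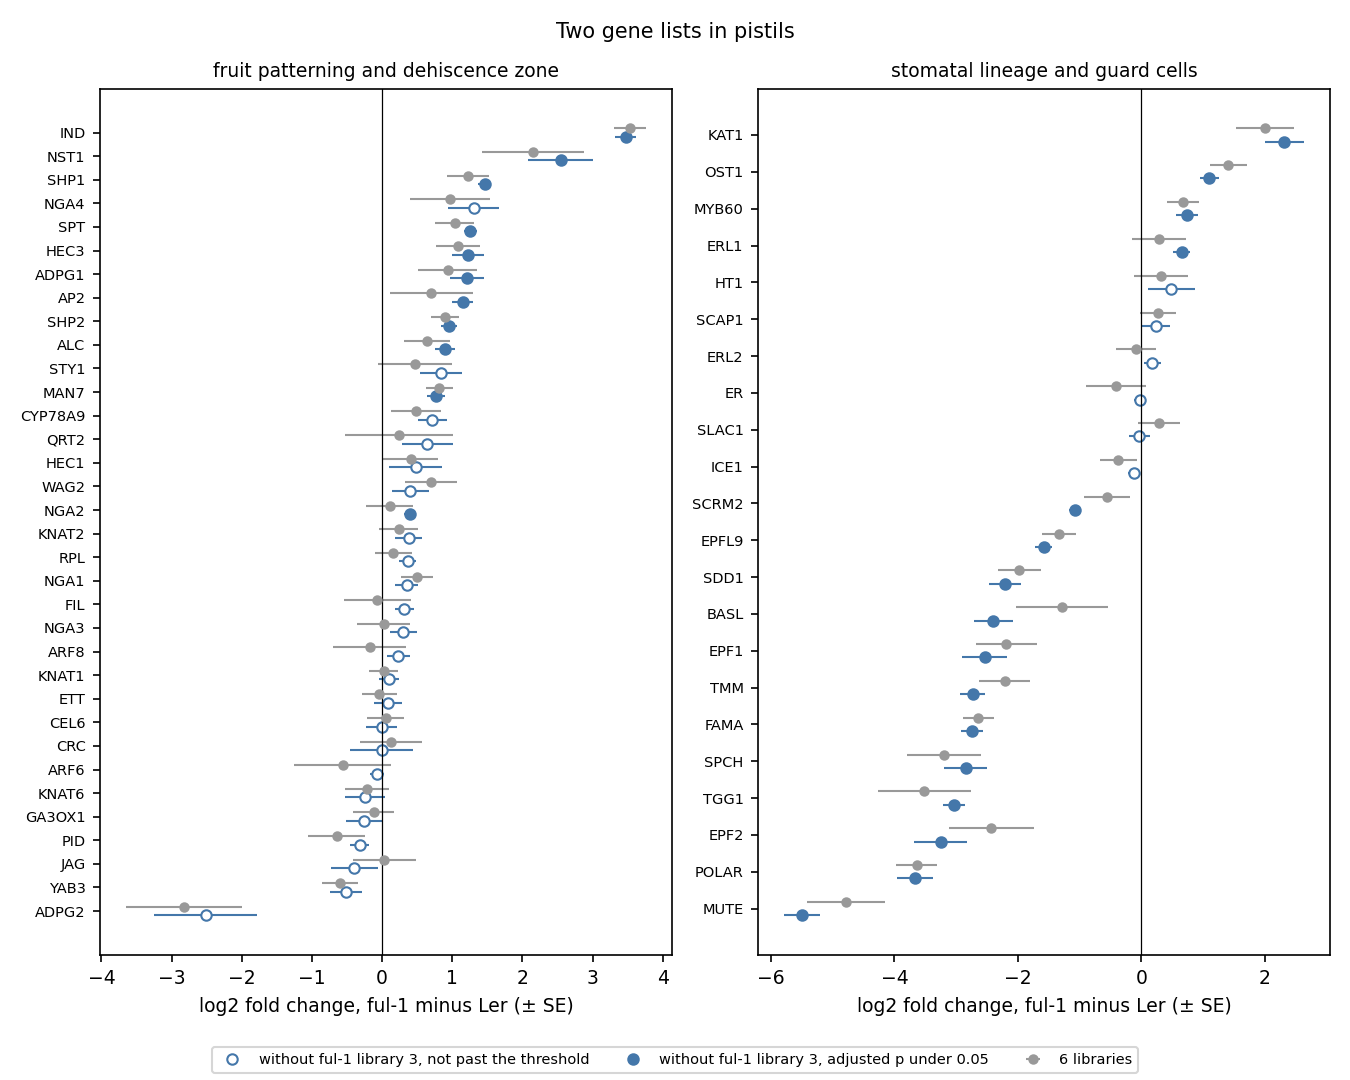
Log2 fold changes, ful-1 minus Ler (x axis), of the tested members of the fruit patterning list (left) and the stomatal list (right), one gene per row, with SE as horizontal lines; grey points are from 6 libraries, whatever their p, and blue points from 5, filled where the edgeR adjusted p was under 0.05. Of the 34 members on the left, 11 filled blue points lie above 0; of the 22 on the right, 12 filled blue points lie below 0 and 4 above.

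Camera placed photosynthesis genes downwards in both pistil fits, and more members passed edgeR's test without the library that stood apart. Over 6 libraries camera gave the list an adjusted p of 0.025 downwards (adjusted p = 0.828 with an estimated correlation), with a median log2 fold change of -0.23. By edgeR 0 of 22 members passed, 4 had an unadjusted p under 0.05, and 3 passed by DESeq2. Adjusted over the list alone, 2 fell. Without ful-1 library 3, 17 of 22 fell, 0 rose and 5 did not pass, and 20 fell when adjusted over the list alone. This came with a camera adjusted p of 3.0e-10 and adjusted p = 0.344 with an estimated correlation. The small subunit genes of Rubisco RBCS3B and RBCS1A changed by -1.31 ± 0.13 and -0.94 ± 0.12, and Rubisco activase, RCA, by -0.81 ± 0.11 (log2, SE). Library 3 itself carried more of these transcripts than its group mates, by a median log2 ratio of 0.72, with LHCB1.3 at 2.82.

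Camera placed the flavonoid and anthocyanin list downwards in ful-1 pistils, at an adjusted p of 0.0042 (adjusted p = 0.779 with an estimated correlation). By edgeR 0 of 10 members passed over 6 libraries, 3 had an unadjusted p under 0.05 and 3 passed by DESeq2. Of these 10, 3 fell when adjusted over the list alone. Without ful-1 library 3, 3 of 11 fell, 0 rose and 8 did not pass, and 4 fell when adjusted over the list alone. Camera then gave 0.017, and adjusted p = 0.752 with an estimated correlation. The 3 were the anthocyanin glycosyltransferase gene UF3GT at -4.54 ± 0.61, the MYB gene PAP1 at -3.02 ± 0.55 and LDOX at -1.38 ± 0.25 (log2, SE). It placed the MADS-box list upwards, at an adjusted p of 0.025 (adjusted p = 0.379 with an estimated correlation). Over 6 libraries 0 of 24 passed by edgeR, 6 had an unadjusted p under 0.05 and 4 passed by DESeq2, and adjusted over the list alone 2 rose and 1 fell. In the 5 libraries 8 of 25 rose, 2 fell and 15 did not pass, and adjusted over the list alone 12 rose and 3 fell. Camera then gave 0.0055, and adjusted p = 0.344 with an estimated correlation. Those that rose included the ovule identity gene STK at 0.82 ± 0.11 and the petal and stamen identity gene AP3 at 0.87 ± 0.10, while SEP4 fell, at -1.55 ± 0.18 (log2, SE). FUL, the mutated gene, is a member and was 1 of the 2 that fell. The MADS-box list shares SHP1 and SHP2 with fruit patterning, and STK and TT16 with the ovule list, so these list results are not separate. Camera also placed the heat shock list upwards, at an adjusted p of 0.013 (adjusted p = 0.367 with an estimated correlation). Of 5 members 0 were past edgeR's threshold, also over the list alone, 1 had an unadjusted p under 0.05 and 0 passed by DESeq2. In the 5 libraries the list had 0.014 (adjusted p = 0.344 with an estimated correlation), with 0 of 5 past edgeR's threshold, 4 at an unadjusted p under 0.05 and 0 by DESeq2.

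The ovule and brassinosteroid lists passed without ful-1 library 3 but not over 6 libraries, a difference that was not tested. Of 13 tested genes of the ovule, seed coat, endosperm and embryo, 5 rose, 0 fell and 8 did not pass, and 9 rose when adjusted over the list alone. Camera gave this list an adjusted p of 0.00017 upwards, and adjusted p = 0.344 with an estimated correlation. INO, an integument gene, rose by 0.90 ± 0.11 and TT2, a regulator of seed coat tannins, by 0.97 ± 0.19 (log2, SE). Of 19 brassinosteroid genes, 4 rose, 1 fell and 14 did not pass, and adjusted over the list alone 8 rose and 2 fell. Here camera gave 0.014 upwards, and adjusted p = 0.344 with an estimated correlation. The biosynthesis genes BR6OX2 and DWF4 rose by 0.86 ± 0.12 and 0.60 ± 0.11, and PRE1, a growth-promoting HLH gene, fell, at -2.66 ± 0.29 (log2, SE). Fry, which tests each list on its own, gave adjusted p values under 0.05 over 6 libraries for the stomatal list (0.0017) and for heat shock (0.030). In the 5 libraries it gave them for these 2 (0.012 and 0.012), photosynthesis (0.012), ovule (0.030), brassinosteroid (0.043) and fruit patterning (0.043). Without ful-1 library 1, the fruit patterning, MADS-box and photosynthesis lists lost their camera calls (adjusted p of 0.153, 0.153 and 0.554). Without ful-1 library 2 so did these 3 and heat shock (0.341, 0.068, 0.341 and 0.053), and without Ler library 2, photosynthesis did (0.051). Omission of other single pistil libraries also gained calls, of cytokinin without Ler library 1 or ful-1 library 1, pollen without Ler library 2 and ovule without Ler library 3.

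The other lists in pistils did not pass camera over 6 libraries. In parentheses are the members past edgeR's test of those tested, those past it when adjusted over the list alone, and camera's adjusted p. Among hormone lists these were cytokinin (0 of 22, 0, 0.057), auxin (0 of 30, 0, 0.873), brassinosteroid (1 of 19, 2, 0.907), gibberellin (0 of 25, 3, 0.971), abscisic acid with proliferative arrest (0 of 23, 4, 0.907), wounding with jasmonate (0 of 24, 1, 0.512) and the SAUR family (0 of 55, 0, 0.656). Among cell wall and growth lists they were expansins (0 of 28, 0, 0.919), xyloglucan endotransglucosylases (0 of 24, 2, 0.558), lignin with secondary wall (0 of 34, 1, 0.512) and cell division (0 of 31, 0, 0.907). Among lists of development they were floral transition with meristem identity (0 of 24, 1, 0.318), meristem maintenance (0 of 21, 0, 0.615), ovule and seed (0 of 11, 0, 0.057), pollen (0 of 11, 0, 0.089) and the circadian clock (0 of 14, 0, 0.374). The tapetum and anther list had 1 tested member, CALS5, at -0.56 ± 0.26 over 6 and -0.58 ± 0.23 over 5 libraries (log2, SE; edgeR adjusted p of 0.499 and 0.155), and no list test. Signs differed in 3 lists that camera placed downwards. The lists of abscisic acid and cell division had medians of -0.18 and -0.11 but means of 0.05 and 0.05, and gibberellin had a median of 0.06 and a mean of -0.15 (log2). Over all lists, 1 gene rose (IND) and 3 fell (FAMA, POLAR and PRE1) among 495 tested in edgeR over 6 libraries, 104 had an unadjusted p under 0.05, and DESeq2 called 52.

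Apart from ovule and brassinosteroid, these lists did not pass camera without ful-1 library 3 either. Parentheses here hold the members that rose and fell of those tested, those past the test over the list alone, and camera's adjusted p. Hormone lists were cytokinin (3 and 0 of 22, 3, 0.250), auxin (0 and 3 of 31, 3, 0.793), gibberellin (4 and 4 of 25, 10, 0.290), abscisic acid (2 and 5 of 24, 8, 0.628), wounding (1 and 1 of 25, 2, 0.793) and SAUR (2 and 5 of 55, 10, 0.178). Cell wall and growth lists were expansins (3 and 2 of 28, 7, 0.333), xyloglucan enzymes (5 and 2 of 24, 9, 0.527), lignin (1 and 3 of 34, 4, 0.431) and cell division (4 and 0 of 31, 5, 0.142). Lists of development were floral transition (3 and 2 of 24, 6, 0.431), meristem maintenance (2 and 1 of 22, 3, 0.333), circadian clock (0 and 1 of 14, 1, 0.793) and pollen (0 and 0 of 11, 0, 0.142), the last with 0 at an edgeR unadjusted p under 0.05 and 0 by DESeq2. Among members that passed in the 5 libraries were the gibberellin-inactivating genes GA2OX8 and GA2OX1 at -4.33 ± 0.36 and -4.16 ± 0.26 (log2, SE). The abscisic acid and cold responsive genes RD29A and COR15A rose by 2.97 ± 0.48 and 2.02 ± 0.38 (log2, SE).

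The meristem comparison asks which transcripts depend on FUL in the inflorescence meristem. TERMINAL FLOWER 1 (TFL1, AT5G03840), which keeps the shoot meristem indeterminate, rose from 10.6 ± 0.432 CPM in Col-0 to 24.0 ± 1.36 CPM in ful-7 (SD, n = 3 each). That was a log2 fold change of 1.18 ± 0.09 (SE) with an edgeR adjusted p of 0.0034. Of the 10 largest increases, 5 were of genes known from the response to iron deficiency. The bHLH genes bHLH38, bHLH39 and BHLH101 rose by 5.63 ± 0.37, 6.18 ± 0.41 and 4.57 ± 0.45 (log2, SE), and the peptide genes AT1G47400 (IMA1) and AT1G47395 (IMA2) by 4.45 ± 0.29 and 4.72 ± 0.55 (log2, SE). The strongest decreases, apart from FUL, were MRD1 at -8.17 ± 0.24, its antisense RNA AT1G07887 at -8.26 ± 0.24 and HEI10 at -3.39 ± 0.13 (log2, SE), which overlap each other. Among 22605 genes tested, 66 passed, 45 higher and 21 lower in ful-7, of which 61 were annotated as protein coding and 3 as pseudogenes or transposable elements.

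The other increases among the 10 largest were the defensin-like gene AT1G13609, from 0.0449 ± 0.0106 to 9.01 ± 1.65 CPM, and AT2G14247, from 0.790 ± 0.569 to 23.9 ± 8.14 CPM (SD, n = 3). AT1G75945 rose by 6.66 ± 0.36 (log2, SE). The long non-coding RNA AT1G07367 rose by 5.58 ± 0.53 and CYP71A13, of camalexin synthesis, by 4.34 ± 0.45 (log2, SE). CYP71A13 shares 22.1% of its exonic length with the antisense gene AT2G30766 (IMA3), which rose by 4.13 ± 0.56. Lower in ful-7 were NEET, an iron-sulfur protein of the chloroplast, from 22.3 ± 5.97 to 2.97 ± 0.929 CPM, and NYC1, a chlorophyll b reductase, from 67.6 ± 13.5 to 18.9 ± 5.56 CPM (SD, n = 3). The rubredoxin-like gene ENH1 changed by -1.83 ± 0.23, AT3G43670 by -2.86 ± 0.35, AT3G49160 by -2.84 ± 0.36 and AT2G36885 by -1.96 ± 0.28 (log2, SE). EdgeR's adjusted p of the 20 genes with the largest changes ran from 1.5e-05 to 0.046, and libraries of the genotypes did not overlap, as the rule that named them required. The call of 66 depended on single libraries. Without ful-7 library 1, 2 or 3, 10, 19 or 31 genes were called. TFL1 lost its call without ful-7 library 1, at an edgeR adjusted p of 0.060, and kept it without any other library (0.0049 to 0.028). There were 29, 26 and 93 genes called without Col-0 library 1, 2 and 3, and DESeq2 called 765.

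**Figure D4:**
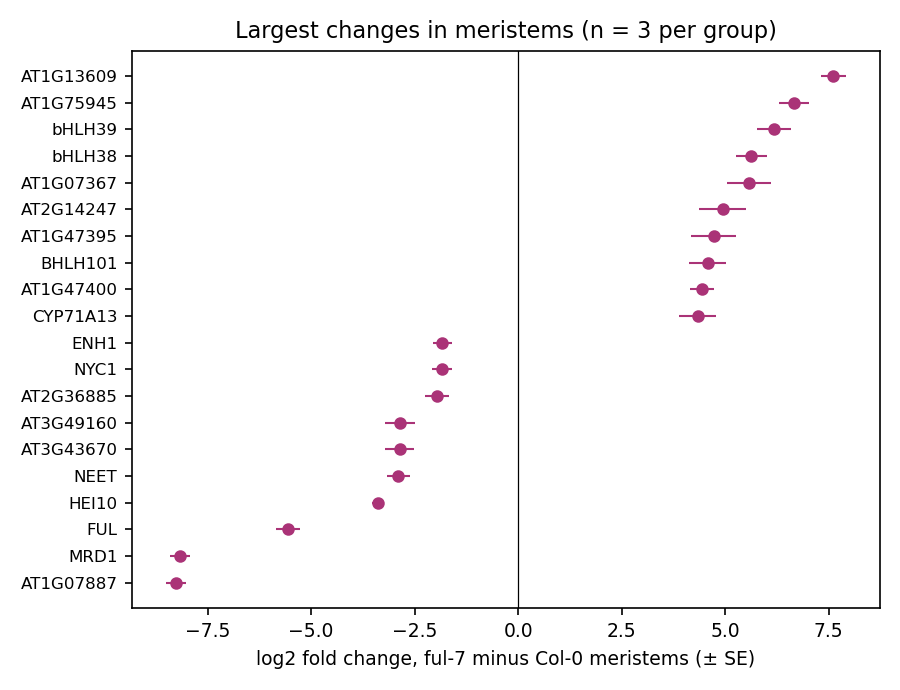
Log2 fold changes, ful-7 minus Col-0 (x axis), of the 10 genes with the largest and the 10 with the lowest values among those past the test in inflorescence meristems (y axis), with SE as horizontal lines (n = 3 per group). Values run from -8.26 for AT1G07887 to 7.61 for AT1G13609.

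Among the list genes in meristems, 3 rose and 1 fell of 472 tested, 109 had an unadjusted p under 0.05 by edgeR and DESeq2 called 32. Of the floral transition and meristem identity genes, TFL1 rose and 26 of 27 did not pass (4 rose and 3 fell when adjusted over the list alone; camera 0.439). The other 2 that rose were LOX2, of jasmonate synthesis, at 1.41 ± 0.20, and XTH15, a cell wall xyloglucan enzyme, at 1.32 ± 0.18 (log2, SE). In the MADS-box list FUL was the 1 of 25 that fell, and 24 did not pass (1 rose and 3 fell when adjusted over the list alone; camera 0.874). This list's median of 0.06 and mean of -0.15 differ in sign. SVP at -0.02 ± 0.11, SOC1 at 0.06 ± 0.08 and AGL24 at 0.18 ± 0.08 did not pass (log2, SE). Nor did AP2 at 0.67 ± 0.19, SHP1 at -0.29 ± 0.12, SHP2 at 0.91 ± 0.38 or ALC at -0.31 ± 0.24 (log2, SE), and IND had too few counts to be tested.

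Camera called 4 lists in meristems, each at an adjusted p of 0.0035: the stomatal lineage and the abscisic acid and proliferative arrest lists downwards, the tapetum and the cell division lists upwards. With an estimated correlation the adjusted p = 0.718 for the stomatal list, 0.850 for abscisic acid, 0.718 for tapetum and 0.851 for cell division, and fry gave adjusted p values of 0.109, 0.411, 0.411 and 0.502. By edgeR 0 of 20 stomatal genes passed, 5 had an unadjusted p under 0.05 and 1 passed by DESeq2, with EPF2, a peptide that limits stomatal density, at -0.87 ± 0.21 (log2, SE). Of 17 abscisic acid and arrest genes 0 passed, 8 had an unadjusted p under 0.05 and 1 passed by DESeq2 (1 fell when adjusted over the list alone), with the phosphatase gene HAI1 at -1.26 ± 0.21 (log2, SE). Of 11 tapetum and anther genes 0 passed, 5 had an unadjusted p under 0.05 and 4 passed by DESeq2 (4 rose when adjusted over the list alone), with the bHLH gene AMS at 0.70 ± 0.15 (log2, SE). Of 31 cell division genes 0 passed, 5 had an unadjusted p under 0.05 and 0 passed by DESeq2, with MCM7, a DNA replication helicase subunit, at 0.66 ± 0.22 (log2, SE). This list lost its camera call without Col-0 library 2 (adjusted p of 0.080) and without ful-7 library 2 (0.090). In all, 7 lists passed without Col-0 library 2 and 7 without ful-7 library 3.

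The remaining lists in meristems did not pass camera. In parentheses are again the members past edgeR's test of those tested, those past it over the list alone, and camera's adjusted p. For hormone lists these were cytokinin (0 of 19, 1, 0.439), auxin (0 of 31, 1, 0.778), brassinosteroid (0 of 18, 0, 0.191), gibberellin (0 of 23, 0, 0.439), wounding with jasmonate (1 of 25, 1, 0.164) and the SAUR family (0 of 55, 0, 0.164). For walls and metabolism they were expansins (0 of 20, 0, 0.669), xyloglucan endotransglucosylases (1 of 18, 3, 0.164), lignin (0 of 31, 0, 0.669), flavonoids (0 of 10, 1, 0.471), photosynthesis (0 of 22, 0, 0.182) and heat shock (0 of 5, 0, 0.905). For development they were fruit patterning (0 of 30, 0, 0.682), meristem maintenance (0 of 25, 0, 0.439), pollen (0 of 10, 0, 0.905) and the circadian clock (0 of 14, 0, 0.669). The ovule list had 3 tested members, with 0 past edgeR's threshold, 0 at an unadjusted p under 0.05 and 0 by DESeq2, and no list test. Signs differed for auxin and heat shock, which camera placed downwards with medians of -0.02 and -0.30 but means of 0.02 and 0.08 (log2).

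The title of the series names target selection by FUL in more than 1 setting, so the effects in pistils and meristems were compared directly. Tissue, ecotype and allele change together between the 2 comparisons and cannot be separated. The change from wild type to mutant differed for 189 of 25154 genes, 48 with a higher and 141 with a lower log2 fold change in pistils than in meristems. Among genes named here, the difference (pistils minus meristems) was 7.91 ± 0.38 for UBC9, 7.22 ± 0.77 for AT3G27473 and 9.82 ± 0.70 for AT4G27980 (log2, SE). AT3G27473 and AT4G27980 had 3 counts in Ler, so their fitted size depends on the prior count. On the other side it was -8.56 ± 0.67 for AT1G04660, -6.68 ± 1.13 for AT2G14247, -6.50 ± 0.63 for AT1G13609, -6.38 ± 1.04 for GA2OX8 and -6.28 ± 1.06 for CYP71A13 (log2, SE). The edgeR adjusted p of these 8 genes ran from 9.4e-06 to 0.024. FAMA and POLAR, called lower in pistils but not in meristems, differed by -2.21 ± 0.26 and -3.40 ± 0.30 (edgeR adjusted p of 0.0033 and 0.00075). LOX2, higher in ful-7 meristems, differed by -3.30 ± 0.44 (edgeR adjusted p of 0.0064). For SHP1, SHP2, ALC and AP2 the difference did not pass by edgeR, at an adjusted p of 0.098 for SHP1 and 0.444 for ALC. Without ful-1 library 3 it passed by edgeR for SHP1, at 1.74 ± 0.14 (SE; adjusted p of 9.1e-05), and for ALC, at 1.20 ± 0.33 (SE; 0.046). It then did not pass for SHP2, at 0.04 (adjusted p of 0.983), or AP2, at 0.47 (0.304). DESeq2 called 1174 genes, and edgeR 2599 without ful-1 library 3. Without ful-1 library 1 or 2 the count was 94 or 147, and without Ler library 1, 2 or 3 it was 58, 71 or 87. Omission of Col-0 library 1, 2 or 3 gave 82, 76 or 102, and of ful-7 library 1, 2 or 3 it gave 57, 65 or 84.

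Genes called in both tissues were 3, all lower in both mutants: MRD1, AT1G07887 and HEI10, which overlap each other. With 21 lower calls in each tissue among 21167 genes tested in both, 0.0208 would be shared by chance (Fisher's exact test, two-sided, p = 1.1e-06, 4.4e-06 adjusted over the 4 pairs of directions). The 3 stem from 1 locus, so the test overstates their number. Of the other pairs of directions, 0 genes were shared with edgeR at the adjusted threshold, where DESeq2 calls shared 8 (higher in both), 7 (higher in pistils, lower in meristems) and 20 (the reverse). By chance these would be 4.61, 3.08 and 7.48 over 31361 genes (Fisher's adjusted p of 0.147, 0.048 and 0.00016). That background includes genes without a DESeq2 adjusted p, which only 25406 genes had in pistils and 23926 in meristems. The DESeq2 chance values are therefore too low and their Fisher p too small. At an edgeR unadjusted p under 0.01 they were 11, 5 and 23, against 4.65, 3.40 and 9.35 by chance (0.0097, 0.398 and 0.00015). Lower in both were 19 by DESeq2, against 5 by chance over the same 31361 genes (Fisher's adjusted p of 3.4e-06), with the same limit. At an edgeR unadjusted p under 0.01 they were 19, against 6.84 (Fisher's adjusted p of 0.00015). FUL and the 3 genes of that locus are included. Without ful-1 library 3, a test added after seeing the data, 7 genes were lower in both, against 1.88 by chance. They include FUL, mutated in both lines, and the 3 genes of 1 locus, so their number is no evidence of shared targets. They were the 3 above, FUL, ENH1 at -0.41 in pistils and -1.83 in meristems, AT2G36885 at -0.93 and -1.96, and AT3G43670 at -1.11 and -2.86 (log2). Over 6 libraries ENH1 stood at 0.09 ± 0.37 in pistils (log2, SE), so its direction there depends on library 3. In that fit LOX2 and AT3G56360 fell in pistils and rose in meristems, where 2.77 would be shared by chance, and KIN2 rose in pistils and fell in meristems, against 1.01 by chance.

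Wild-type levels show where these genes were expressed, with tissue and ecotype confounded. Between Ler pistils and Col-0 meristems 14614 of 24009 genes differed, 7636 higher and 6978 lower in pistils, by edgeR's test. FUL itself stood at 105 ± 5.31 and 121 ± 32.5 CPM (SD, n = 3; edgeR adjusted p of 0.364). SHP1 stood at 84.7 ± 8.34 CPM in pistils and 10.3 ± 0.556 CPM in meristems, SHP2 at 69.2 ± 8.17 and 1.47 ± 0.663 CPM (SD, n = 3 each). ALC stood at 84.2 ± 13.6 and 34.5 ± 13.3 CPM, and AP2 at 48.0 ± 5.73 and 14.2 ± 3.37 CPM. SVP stood at 2.37 ± 0.480 CPM in pistils and 43.7 ± 5.33 CPM in meristems, SOC1 at 9.13 ± 2.49 and 84.9 ± 3.49 CPM, and AGL24 at 0.630 ± 0.120 and 35.6 ± 2.74 CPM (SD, n = 3 each). TFL1 was lower in pistils than in meristems, where it stood at 10.9 ± 0.554 CPM (SD, n = 3), by a log2 fold change of -3.32 ± 0.18 (SE).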

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

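The tests of gene length, of a mistaken Ler label, of linkage between neighbouring calls and of the neighbouring run in meristems were chosen only after the result was seen, as was the omission of ful-1 library 3 for overlap and named genes; the others were set before their own values were computed, those on the run, the MRD1 locus and the iron genes after these patterns had been seen. A test of the difference of the effect between tissues found 189 genes, and named members with an adjusted p under 0.05 by edgeR are given here for that reason. Differences are log2 fold changes in pistils minus those in meristems. Their edgeR adjusted p ran from 9.4e-06 to 0.048. Tissue, ecotype and allele changed together between both comparisons.

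The largest positive differences lay in genes near 0 in Ler pistils, and the fitted size depends on the prior count where Ler had 3 or fewer counts. They were 12.32 for YLMG1-2, 9.82 for AT4G27980, 7.91 for UBC9, 6.37 for SLAH2, 5.28 for CRF4 and 4.96 for AT4G27940, all in the run of neighbouring genes. Outside it AT2G06002 had 9.77, AT3G27473 7.22, AT4G14548 4.58 and the overlapping pair AT3G22125 and AT3G22142 3.59 and 3.58. Stress-responsive RD29A and COR15A had 4.55 and 2.57, and AT3G49160, lower in ful-7 meristems, had 3.52.

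Negative differences covered several groups of genes. Of the stomatal lineage, FAMA had -2.21, POLAR -3.40 and MUTE -4.66. Of hormone and growth genes, PRE1 had -3.03, LOX2 -3.30, GA2OX1 -3.67 and GA2OX8 -6.38. Of flavonoid synthesis, LDOX had -3.40 and UF3GT -4.89, both with a near-identical stretch in another gene. Of genes linked to light and plastids, RBCS3B had -1.34, PKS2 -4.84 and CGA1 -5.91. The flowering gene SPL15, whose exons lie wholly within those of a gene on the other strand, had -1.74. CORI3 had -5.69, SHN2 -5.90, SCPL9 -4.25, AT1G11850 -5.66, AT3G56360 -2.58 and AT1G04660 -8.56. AT1G13609 had -6.50, AT2G14247 -6.68, CYP71A13 -6.28 and BHLH101 -4.88. BHLH101 had too few counts to be tested in pistils alone, so its difference rests mainly on its rise in ful-7 meristems and does not show another effect in pistils. Among iron genes chosen after their values had been seen, FER1, a ferritin, had 3.21, ORG1 -1.67, FRO3 -2.01 and IMA3 -5.60.

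Ful-1 pistil library 3 stood apart from the other 5 pistil libraries. A Ler library under a ful-1 label was argued against by FUL, which stood at 1.90% of the lowest Ler library in CPM without TMM scaling. A bias with transcript length, as degraded RNA or library preparation could give, fitted the data. Across genes, which are not independent replicates, the log2 ratio of library 3 to its group mates correlated with exonic length at Spearman's rho of -0.312. The most extreme other pistil library had -0.231. Col-0 meristem library 3 had 0.287, so a trend of nearly this size was not particular to the ful-1 library. The ful-1 library's median log2 ratios, from CPM without TMM scaling, were -0.23 and -1.55 in genes with under 1153 and over 2338 exonic bases. Other cells or another stage in the dissection stayed open. The highest median log2 ratio over lists of other cell types or states was 0.718, for photosynthesis. It lay between the bounds of 0.5 and 1 set for this test. That ratio came from TMM-scaled CPM, so it is not on the scale of the medians by length. Photosynthesis members had a median exonic length of 1372 bases, and the ratio was not adjusted for length. No biological explanation was tested, since this library shares its genotype and tissue with its mates.

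Calls in pistils included genes that lie side by side in order of locus code. Of 41 calls, with overlapping genes counted once, 5 had another call within 3 places in that order. All 5 lay in 1 run of genes that was seen before this test was chosen, and 0 lay outside it. Some codes do not follow position, so calls beside each other on the chromosome could be missed. The test thus gave no evidence on a linked segment that differs between the strains, which stayed open. In the run from AT4G27940 to AT4G28000, near 0 in Ler, 6 of the 7 genes had at least 1.56 CPM in each other group, and AT4G28000 had 0.117 and 0.0828 CPM in the meristems (without TMM scaling). Shared reads were argued against (0 of 7 genes overlap or match another gene of the run), as was loss of FUL acting in both tissues (median log2 fold change of 0.288 in ful-7 meristems); a segment lacking in Ler relative to the reference, and present in the ful-1 plants, stayed open and was not tested on sequence. For MRD1, AT1G07887 and HEI10, lower in both mutants, shared reads fitted, since MRD1 and AT1G07887 overlap over at least 83.1% of their exonic length. A wider segment was argued against by the 4 tested genes nearest by locus code, whose median was -0.089 at its farthest from 0. Whether FUL acts on the MRD1 locus, or whether each mutant carries another variant there, cannot be read from these counts.

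Of 24 tested iron-deficiency genes, 11 rose in ful-7 meristems and 0 fell. The lowest median over the 6 fits without 1 library was 1.04. The list was written partly from genes that stood out in these same libraries, so a high median was likely from the start. This check therefore gives no independent evidence on dependence on 1 library. Gene length bias was argued against by genes matched on length and level, whose median was -0.024. Loss of FUL acting in both tissues was argued against only for the 16 members tested in ful-1 pistils, whose median was -0.171. The strong risers bHLH38, bHLH39, BHLH101, IMA1 and IMA2 had too few counts there, so the question stayed open for them. Loss of FUL in the meristem and a difference in iron supply between trays or harvests both stayed open and untested, since no label gives tray or date, and the former would be a hypothesis only.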

How the results depend on the processing

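The omission of ful-1 library 3 in the overlap of calls and in the named genes was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the columns carry no replicate numbers, and fits with a replicate block were not run for the same reason. In pistils DESeq2 called 872 genes and the fit of all 12 libraries 647, against 44; in meristems DESeq2 called 765, no filter 153 and the fit of all 12 libraries 26, against 66; for the difference DESeq2 called 1174, against 189; the cause was not tested. With an estimated correlation 0 lists passed in pistils and 0 in meristems, against 6 and 4, and with fry 2 and 0. For the overlap of calls, genes higher in both were 11 at an unadjusted p under 0.01; those higher in pistils and lower in meristems were 7 by DESeq2; those lower in pistils and higher in meristems were 23 at an unadjusted p under 0.01 and 20 by DESeq2, where 0 had been shared, and those lower in both were 19 in each, against 3; the cause was not tested. Without 1 library in turn the counts ran from 0 (without a Ler library) to 3221 (without ful-1 library 3) in pistils, from 10 to 93 in meristems, from 57 to 2599 for the difference and from 12476 to 15705 between wild types, and lists passing from 2 to 8 in pistils and from 3 to 7 in meristems; fewer libraries also mean fewer degrees of freedom. Over these fits CDC20.2 in pistils ran from -0.46 to 0.43 and ENH1 from -0.41 to 0.31 (log2), and the direction of both turned without ful-1 library 3, where both passed; the cause was not tested. DESeq2's size factors in edgeR and the strict filter left each count within 1.5 times its value. The threshold on size left 44 genes in pistils, 55 in meristems, 187 for the difference and 8013 between wild types, and omission of organelle genes, run within tissues only, gave 46 and 66. Of lists not called over 6 pistil libraries, cytokinin passed camera without Ler library 1 (adjusted p of 0.045) or ful-1 library 1 (0.014), pollen without Ler library 2 and ovule without Ler library 3 (0.039). Of the named genes past the threshold, 24 of 24 in pistils and 25 of 25 in meristems, and 11 of 11 of those named for their difference, were also called by DESeq2, in the same direction. Without 1 library other than ful-1 library 3, at most 1 of the 24 in pistils was called, and in meristems 9 to 22 of the 25 were. FUL stood at 7.52 CPM in ful-1 and 2.44 CPM in ful-7 without TMM scaling. Depth was lowest in ful-1 library 3, where FUL had 25 counts.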

Other observations

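The lists of iron genes were written only after the result was seen, and their members are partly those that stood out, so their p-values are not independent evidence. Of 24 tested genes known to rise under iron deficiency, 11 rose in ful-7 meristems, 0 fell and 13 did not pass, and camera gave an adjusted p of 3.2e-17, with adjusted p = 0.231 with an estimated correlation and 0.0040 by fry. IMA2 rose from 1.75 ± 1.48 to 46.7 ± 10.4 CPM, IMA3 from 3.04 ± 2.23 to 53.0 ± 9.15 CPM and bHLH38 from 0.170 ± 0.122 to 7.80 ± 0.201 CPM (SD, n = 3 each). The ferric reductase gene FRO3 changed by 1.34 ± 0.10, the phloem transporter gene OPT3 by 1.35 ± 0.16, the E3 ligase gene BTS, a brake on the response, by 0.89 ± 0.08, ORG1 by 1.30 ± 0.13 and CGLD27 by 1.73 ± 0.23 (log2, SE). The bHLH genes PYE and FIT, at 0.69 ± 0.19 and 0.45 ± 0.33, did not pass in edgeR (adjusted p of 0.221 and 0.537).

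Of 8 tested genes of iron storage and of proteins that hold iron, 0 rose in ful-7 meristems, 5 fell and 3 did not pass, and camera gave an adjusted p of 2.9e-10, with adjusted p = 0.279 with an estimated correlation and 0.016 by fry. Ferritin FER4 changed by -1.82 ± 0.17, the stromal ascorbate peroxidase SAPX by -1.14 ± 0.09, ABCI8 by -1.19 ± 0.16, and NEET and ENH1 as given above (log2, SE). Ferritins FER1 and FER3 had values of -2.14 ± 0.39 and -1.15 ± 0.24 and did not pass in edgeR (adjusted p of 0.102 and 0.151). In ful-1 pistils the list of rising genes had 16 tested members, without bHLH38, bHLH39, BHLH101, IMA1 and IMA2, and a camera adjusted p of 0.640.

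Other splits of the same libraries into equal groups show how often a count as large arises. For 6 libraries 10 splits exist, too few for a share under 0.05. The real split gave 44 genes in pistils, 66 in meristems and 14614 between wild types, where the highest other split gave 0 in each case, so 1 of 10 splits reached the real count. Of the 10 splits 4 reached the 6 lists of the real split in pistils, with 8 the highest other value, and 8 of 10 reached the 4 lists in meristems, with 13 the highest. Whether the 13 lists of another split of the meristem libraries stem from a structure of these samples or from correlation between genes was not tested. For the difference between tissues 1 of 100 splits reached the 189 genes of the real split. The highest other value, 144, came from the real groups with the sign of the meristem effect reversed. These splits regroup libraries within each tissue, so they bear on an effect in either tissue. They cannot show that the effects differ between tissues.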
